A study of Caenorhabditis elegans with 6 samples.

How the data were processed

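The samples were 6 poly(A) RNA-seq libraries from Caenorhabditis elegans embryos, 2 for each of 3 groups: wild type at 26 °C, the let-418 L781F mutant at 20 °C and the same mutant at 26 °C. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the KAPA RNA HyperPrep kit. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, STAR 2.5.4b and HTSeq 0.9.1 with genome build ce11. The deposited values are whole-number counts of reads per gene, 1 file per library, with no normalization by the authors. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes may be mixed. Of the genes picked, 7 have over 10% of their exon bases under an opposite-strand gene: dod-18 (40.8%), ceh-22 (23.4%), sip-1 and tnc-2 (19.2% each), ugt-22 (14.3%), hsp-17 (13%) and mlc-2 (12%).

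Each file lists 46904 gene identifiers, of which 46817 are in the Ensembl 115 annotation of WBcel235, the assembly also called ce11, and 44017 have a symbol in the gene name table. Coordinates are from that annotation. The 5 summary lines per file that name no gene were kept out of library sizes and tests. They held 4.65% and 4.5% of the records in the wild-type libraries, 38.5% and 6.04% in the 20 °C mutant and 7.11% and 17.4% in the 26 °C mutant, and reads placed at several positions were counted there. Gene counts summed to 20145538 to 33503205 per library, and totals outside ribosomal RNA ranged from 5266529 to 33408894. Near-identical copies, such as the hsp-16 pairs and core histone genes, lose reads at counting, and their values are uncertain.

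Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, in 1 fit of all 6 libraries with group as the only term. The fit held 16187 genes, with 3 residual degrees of freedom and a prior of 8.84. Adjusted p-values are from the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. Fold changes are log2 values with a standard error from the fold change and the square root of the F statistic. CPM values use TMM effective library sizes, and ± after CPM is the SD of 2 libraries. Replicates differed by more than sampling noise (chi-square over degrees of freedom 33.2 in wild type, 44.9 in the 20 °C mutant and 16.3 in the 26 °C mutant), so none was treated as a duplicate. Because the groups have 2 libraries each, non-overlapping groups arise by chance for 33.3% of genes.

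The design, the alternatives, 32 gene lists and the rule for named genes were fixed before the data were examined. Of the lists, 31 had at least 5 measured members and were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01. Lists were also tested with a correlation estimated from the data, with which 0 lists passed in any comparison. The estimate lay below the preset value for heat shock (0.009) and ciliary genes (-0.007). Correlated members thus do not account for the higher p-values of these lists. For other lists it was higher, up to 0.874 for ribosomal protein genes. That test also takes the 3 residual degrees of freedom of the fit, which by itself raises p-values. A further test was fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. The rule named let-418, chd-3, nurf-1 and isw-1. It also named the 10 largest rises and falls in each of the first 2 comparisons and 5 in the third, among protein-coding genes with a locus name, a mean of at least 10 CPM in the higher group and no overlap between libraries, histone and msp genes left out. From each list it named up to 2 called members per direction with the smallest p, and up to 10 genes per direction called alike in both comparisons of the 26 °C mutant. The mitochondrial list was taken as the 12 protein-coding genes of the mitochondrial chromosome, since the symbols differ between tables.

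Folds against a group at 0 reads use a floor of 3 counts over the group. With 1 to 3 reads a ratio with an exact 95% Poisson interval is given. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

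The analysis was tested on simulated counts made from the real means and library sizes, with 200 changed genes. For the 26 °C mutant against wild type (15633 genes fitted) it recovered 7.5% of 1.5-fold, 55.2% of 2-fold and 95.5% of 4-fold changes, with 3 false calls. Against the 20 °C mutant (15586 genes) it recovered 4.5%, 59.7% and 97% of these sizes, with 5 false calls, and for the 20 °C mutant against wild type (15604 genes) 13.4%, 58.2% and 93.9%, with 3 false calls. The simulation gave all groups the same spread at a given level. The SD of the log2 difference between real replicates was 0.431 in wild type, 1.187 in the 20 °C mutant and 0.538 in the 26 °C mutant. These rates therefore do not cover unequal spread or differences in ribosomal RNA and length trend. Alternatives were DESeq2 size factors (RLE), no filter, a filter of 5 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits of only the 4 libraries compared, the replicate number as a block, protein-coding genes only and each library left out. Added after seeing the data were fits without ribosomal RNA genes, without both libraries in which ribosomal RNA took over 10% of gene counts, with counts outside ribosomal RNA thinned to the 5266529 of the smallest library, with each library's trend on exon length as an offset, and a crossed replicate block. The genome sequence was not used here, so GC content was not checked.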

Results

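Poly(A) RNA was sequenced from Caenorhabditis elegans embryos in 3 groups of 2 libraries. One group was wild type at 26 °C. Both other groups carried the L781F change in LET-418, a CHD4-like ATPase of the NuRD chromatin remodelling complex, and were kept at 20 °C or at 26 °C. The series concerns a clinical NuRD variant whose sterility is rescued by inhibiting NURF, another chromatin remodeller. Wild type at 20 °C was not analysed here, so temperature could be compared only within the mutant and genotype only at 26 °C. Gene counts per library ranged from 20145538 to 33503205. Ribosomal RNA took 73.9% of the gene counts in 20 °C mutant replicate 1 and 21.6% in 26 °C mutant replicate 2. In the other 4 libraries its share lay between 0.186% and 1.46%. Outside ribosomal RNA the depth was 5266529 counts in 20 °C mutant replicate 1 and 25179345 to 33408894 elsewhere. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 71.6% of the variance and separated the 20 °C mutant libraries from the 4 libraries made at 26 °C.

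The mutated gene itself was read first. let-418 (WBGene00002637, WBcel235 chromosome V, 5826833 to 5832831, plus strand) had 151 ± 24.4 CPM (counts scaled to library size, SD, n = 2) in wild type at 26 °C. It had 414 ± 124 CPM in the mutant at 20 °C and 205 ± 7.19 CPM in the mutant at 26 °C. The change is a single residue, so the transcript level does not check the genotype. At 26 °C the mutant and wild type did not differ past the threshold (log2 fold change 0.44 ± 0.21 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.121). Within the mutant, let-418 fell by 1.01 ± 0.21 on the log2 scale from 20 to 26 °C (adjusted p = 0.00145), a call that ended without 26 °C mutant replicate 1 (adjusted p = 0.0879) or replicate 2 (0.0557).

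The first comparison asked how embryos with the LET-418 change differ from wild type at 26 °C. Heat shock genes were among the largest rises. hsp-70 (WBGene00002026, chromosome I, 9320325 to 9322519, minus strand), an inducible HSP70 chaperone, rose 56.7-fold, from 7.84 ± 0.307 to 445 ± 0.406 CPM (SD, n = 2 each). The small heat shock gene hsp-16.2 rose 19.6-fold, to 1698 ± 33.2 CPM, and the HSP70-family gene F44E5.5 rose by 4.09 ± 0.18 on the log2 scale. rnh-1.3, a ribonuclease H gene, rose 33.6-fold to 262 ± 7.43 CPM. nurf-1, the gene of the largest NURF subunit, rose 4.06-fold, and 29 of 41 ciliary genes fell.

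Of the 27 measured members of the cytosolic heat shock list, 24 rose, 0 fell and 3 did not pass the test, with a median log2 fold change of 1.84. Adjusted over the list alone, 25 rose and 0 fell. The list test with a preset correlation gave an adjusted p of 3.02e-14, and adjusted p = 0.0843 with an estimated correlation. Outside the rule for named genes and chosen after their values were seen, hsp-110 rose by 3.13 ± 0.20, the J-domain gene dnj-13 by 2.07 ± 0.17 and hsp-90 by 1.79 ± 0.20 on the log2 scale. The gene of the heat shock transcription factor, hsf-1, also named outside the rule, had a log2 fold change of 0.11 ± 0.17 (adjusted p = 0.666). The hsp-16 genes lie in near-identical pairs, as do F44E5.4 and F44E5.5, so reads shared between copies make their single values uncertain. The summed level of the list was 2149 and 2160 CPM in the wild-type libraries and 9534 and 9157 CPM in the 26 °C mutant libraries.

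**Figure D1:**
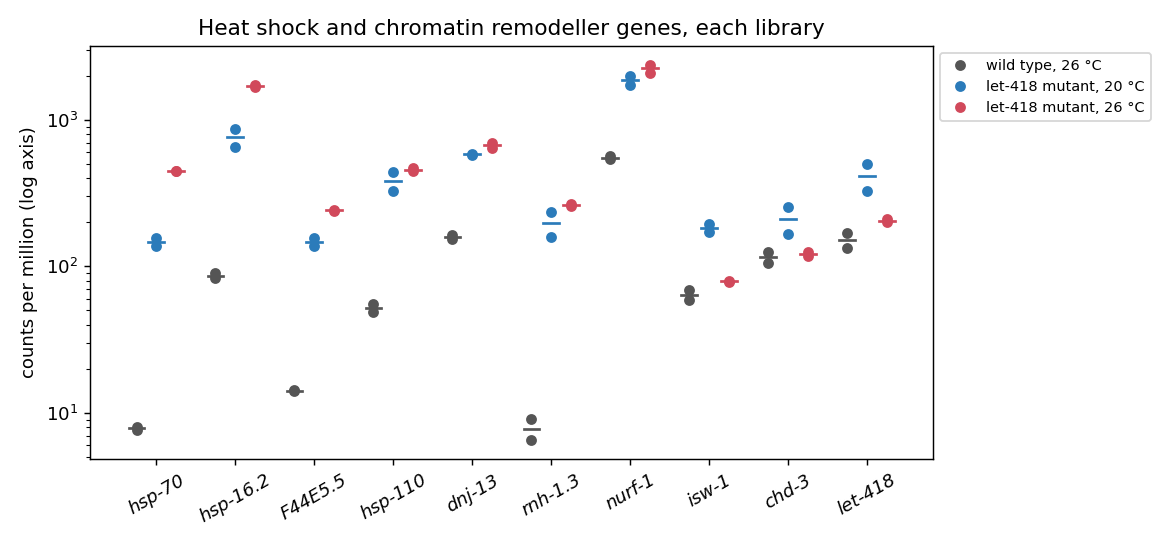
CPM (log axis) of heat shock and chromatin remodeller genes in each of the 6 libraries; points are libraries and short lines are group means. hsp-70 lies at 7.63 and 8.06 CPM in wild type and above 137 CPM in every mutant library, and nurf-1 at 541 and 563 CPM in wild type and from 1741 to 2378 CPM in the mutant libraries.

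Of the genes of both remodelling complexes, nurf-1 (WBGene00009180, chromosome II, 14390713 to 14407911, plus strand) changed most. It rose by 2.02 ± 0.21 on the log2 scale, from 552 ± 15.5 to 2240 ± 195 CPM (SD, n = 2, adjusted p = 6.42e-05), and its exons overlap 0 bases of other annotated genes. In the NURF and ISWI list 3 of 6 members rose and 0 fell (3 and 0 adjusted over the list alone). Besides nurf-1 these were lin-53, a histone-binding subunit also found in NuRD (0.99 ± 0.16), and pyp-1 (0.95 ± 0.18), named outside the rule after its values were seen. isw-1, the ATPase of NURF, had a log2 fold change of 0.31 ± 0.16 (adjusted p = 0.153), and chd-3, the other CHD4-like gene, 0.07 ± 0.20 (adjusted p = 0.817). The NURF list test gave adjusted p = 0.0171, and 0.232 as the adjusted p with an estimated correlation; without both libraries rich in ribosomal RNA, chosen after seeing the data, it was 0.0695, and without wild-type replicate 2 it was 0.0548, with list medians of 0.66 and 0.69 against 0.66. Without wild-type replicate 2 the lin-53 and pyp-1 calls ended (adjusted p = 0.094 and 0.0771), and likewise without 26 °C mutant replicate 1 (0.118 and 0.109). Without 26 °C mutant replicate 2 that of lin-53 ended (0.0766). In the NuRD and MEC list 3 of 10 rose, among them lin-40 (0.54 ± 0.16), and 1 fell, egl-27 (-0.51 ± 0.17). The list test gave adjusted p = 0.228. Leaving out any library of this comparison ended both gene calls (adjusted p from 0.0801 to 0.457 for lin-40 and from 0.114 to 0.288 for egl-27).

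Ciliary genes and some neuronal genes fell. Of 41 genes of cilia and intraflagellar transport, 29 fell, 0 rose and 12 did not pass (30 and 0 adjusted over the list alone), with a median of -0.99. The dynein heavy chain gene che-3 fell by 1.84 ± 0.27, from 39.6 ± 3.72 to 11.1 ± 0.519 CPM (SD, n = 2), the BBSome gene bbs-2 fell by 1.56 ± 0.19 and the transition zone gene mks-6 by 1.47 ± 0.16. The list test gave adjusted p = 7.72e-09, and adjusted p = 0.0843 with an estimated correlation. Among 57 neuronal genes 14 fell and 6 rose (14 and 6 adjusted over the list alone; list test adjusted p = 0.00158, and adjusted p = 0.178 with an estimated correlation). The kinesin gene unc-104 fell by 1.38 ± 0.19 and rgef-1, a pan-neuronal marker, by 1.72 ± 0.22. In the excretory and glial list 9 of 21 fell, with ptr-10 at -1.01 ± 0.16, and 3 rose (11 and 3 adjusted over the list alone; list test adjusted p = 0.00702, and adjusted p = 0.205 with an estimated correlation). Log2 fold change followed exon length across 10396 genes (Spearman rho = -0.382; genes are not independent replicates), and the ciliary list has a median exon length of 2330 bases.

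Genes of the cytosolic ribosome were higher almost without exception. Of 77 ribosomal protein genes, 75 rose, 0 fell and 2 did not pass (75 and 0 adjusted over the list alone), with a median of 1.31. Examples are rpl-25.2 (1.74 ± 0.22) and rpl-30 (1.70 ± 0.21), the latter from 194 ± 16.3 to 630 ± 68 CPM (SD, n = 2). The list test gave adjusted p = 5.97e-22, and adjusted p = 0.441 with an estimated correlation. These genes are short, with a median exon length of 532 bases. Cell cycle and DNA replication genes rose in 21 of 42 cases and fell in 0 (24 and 0 adjusted over the list alone; list test adjusted p = 6.61e-05, and adjusted p = 0.232 with an estimated correlation). The centromeric histone gene hcp-3 rose by 1.42 ± 0.18. In the synMuv B and DREAM list 6 of 16 rose and 0 fell (7 and 0 adjusted over the list alone), with efl-1, an E2F gene, at 1.12 ± 0.17 (list test adjusted p = 0.0217, adjusted p = 0.232 with an estimated correlation, and 0.072 without both libraries rich in ribosomal RNA). Without 26 °C mutant replicate 2 or wild-type replicate 2 its adjusted p was 0.0571 or 0.0866. The list median was 0.35 with all libraries and 0.33 to 0.37 in these 3 settings. Endoplasmic reticulum and mitochondrial chaperone genes rose in 11 of 23 cases and fell in 2 (11 and 3 adjusted over the list alone). The BiP gene hsp-4 rose by 1.55 ± 0.17 and the stress sensor gene ire-1 fell by 1.03 ± 0.19. The list test gave adjusted p = 0.0228, with an estimated correlation adjusted p = 0.375, without ribosomal RNA genes 0.0508 and without both libraries rich in them 0.0629. Without 26 °C mutant replicate 1 or wild-type replicate 2 it was 0.0688 or 0.161. The list median went from 0.39 to between 0.28 and 0.35 in these 4 settings.

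Some genes of the cuticle and of immune defence rose. Of 137 cuticle collagen genes 66 rose and 0 fell (67 and 0 adjusted over the list alone; median 0.82, list test adjusted p = 7.72e-09, and adjusted p = 0.441 with an estimated correlation). col-122 (5.68 ± 0.46) and col-124 (5.36 ± 0.47) were among them at low levels, 5.55 ± 0.817 and 5.92 ± 0.486 CPM in the 26 °C mutant. Innate immune effector genes rose in 14 of 25 cases and fell in 1 (14 and 1 adjusted over the list alone; list test adjusted p = 0.00606, and adjusted p = 0.346 with an estimated correlation), with the antimicrobial peptide gene nlp-29 up by 2.17 ± 0.19 to 270 ± 22.2 CPM. In the intracellular pathogen response list 7 of 19 rose and 0 fell (7 and 0 adjusted over the list alone), among them pals-14 (1.41 ± 0.25; list test adjusted p = 0.0217, and adjusted p = 0.346 with an estimated correlation). Vitellogenin genes, which encode yolk proteins of the adult intestine, rose in 5 of 6 cases and fell in 0 (5 and 0 adjusted over the list alone; list test adjusted p = 0.000427, and adjusted p = 0.178 with an estimated correlation). Their level stayed low: vit-2 had 419 reads in the 26 °C mutant and 2 in wild type, a ratio of 309 with a 95% counting interval from 84.9 to 2560. Histone genes rose in 23 of 41 cases and fell in 0 (31 and 0 adjusted over the list alone, list test adjusted p = 0.000259, and adjusted p = 0.559 with an estimated correlation). The histone list summed to 1818 and 2027 CPM outside ribosomal RNA in wild type and to 3422 and 3611 in the 26 °C mutant, whose ribosomal RNA shares were 0.186% and 21.6%. Most of each sum came from a few genes, among them his-71 and his-72. These held 1515 and 1636 CPM in wild type and 2728 and 2424 CPM in the 26 °C mutant. The median histone gene, relative to its mean over all libraries, lay at -2.45 and -1.79 in wild type and at -1.11 and 0.34 in the mutant on the log2 scale, so the typical rise was larger in the replicate rich in ribosomal RNA.

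Among detoxification and F-box genes more fell than rose, and most did not pass the test. Cytochrome P450 and UGT genes fell in 42 of 117 cases and rose in 10 (43 and 10 adjusted over the list alone; list test adjusted p = 8.14e-05, and adjusted p = 0.178 with an estimated correlation), with cyp-35A4 down by 1.81 ± 0.22. F-box and MATH-BTB genes, which encode substrate adaptors of ubiquitin ligases, fell in 78 of 313 cases and rose in 31 (76 and 30 adjusted over the list alone; list test adjusted p = 0.00264, and adjusted p = 0.205 with an estimated correlation). fbxb-17 fell by 2.23 ± 0.20, a 4.68-fold drop from 59.2 ± 10.9 CPM (SD, n = 2). The chemoreceptor gene srw-85 fell by 2.94 ± 0.38, fbxa-107 by 2.84 ± 0.34 and the methyltransferase-like gene metl-13 by 2.81 ± 0.25, the 3 largest falls under the rule for named genes. DESeq2 gave srw-85 an adjusted p of 0.0607. Other large rises were nspe-7 (4.32 ± 0.28), the antimicrobial peptide gene cnc-6 (3.65 ± 0.31) and the superoxide dismutase gene sod-5 (3.63 ± 0.26).

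The lists for germ granules, meiosis, small RNA, maternal and early zygotic genes and muscle held genes called in both directions and did not pass the list test. Germ granule genes rose in 5 of 28 cases and fell in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.112), with the helicase gene glh-1 up 3.88-fold from 10.6 ± 0.0457 CPM. Meiosis genes rose in 8 of 35 cases, among them the cohesin gene rec-8 (1.54 ± 0.16), and fell in 7, among them him-8 (-1.18 ± 0.16; adjusted p = 0.835; 9 and 8 adjusted over the list alone). Germline small RNA genes rose in 9 of 32 cases, with the Argonaute gene ppw-2 at 2.33 ± 0.26, and fell in 8, with the RNA polymerase gene rrf-1 at -1.29 ± 0.21 (adjusted p = 0.835; 9 and 8 adjusted over the list alone). Maternal genes rose in 6 of 39 cases and fell in 5 (6 and 4 adjusted over the list alone; adjusted p = 0.507). Early zygotic genes rose in 2 of 26 and fell in 8 (3 and 9 adjusted over the list alone; adjusted p = 0.197). Muscle genes rose in 6 of 40 and fell in 13, with the calcium channel gene egl-19 down by 1.79 ± 0.22 (6 and 14 adjusted over the list alone; adjusted p = 0.1).

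In all, 3411 of 16187 tested genes were higher and 2649 lower in the mutant than in wild type at 26 °C (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and with no filter on low counts 2505 were higher and 2951 lower. Leaving out ribosomal RNA genes (2451 higher, 2701 lower) or keeping only protein-coding genes (2448 and 2684) also turned the balance. RLE size factors (3189 and 2612) and thinning to equal depth (2951 and 2079) kept it. Which direction held more genes thus depended on the processing. Counts fell to 1219 higher and 783 lower without wild-type replicate 1, 933 and 1226 without wild-type replicate 2, 1021 and 902 without 26 °C mutant replicate 1, and 1407 and 1221 without 26 °C mutant replicate 2. With only the 4 libraries compared, 4034 were lower, and 4040 or 4039 were lower without 20 °C mutant replicate 1 or 2.

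**Figure D2:**
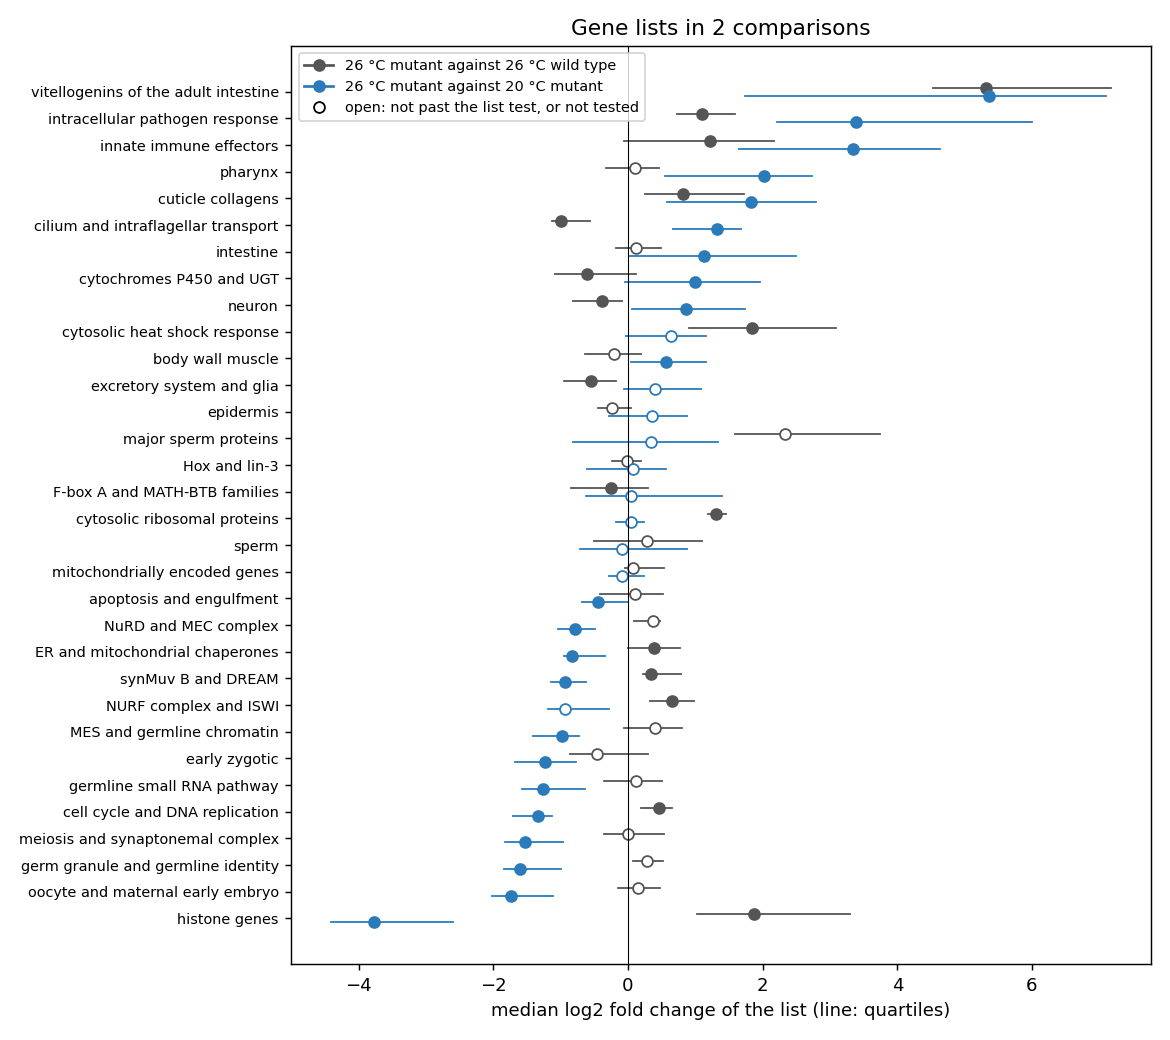
Median log2 fold change of each of the 32 gene lists (lines: quartiles of the members) for the 26 °C mutant against 26 °C wild type and against the 20 °C mutant; filled points passed the list test with a preset correlation. Cilium genes lie at -0.99 against wild type and 1.33 against the 20 °C mutant, and heat shock genes at 1.84 and 0.63.

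The second comparison asked how the mutant embryos differ between the permissive 20 °C and 26 °C. Most listed genes of the oocyte, germ line and dividing early embryo were lower at 26 °C, and many genes of differentiated tissues were higher. The germ granule gene pgl-3 fell by 2.91 ± 0.31 and the oocyte kinesin gene klp-15 by 2.88 ± 0.20, from 34.7 ± 3.17 to 4.74 ± 0.444 CPM (SD, n = 2). The synaptotagmin gene snt-1 rose by 3.20 ± 0.18, from 5.41 ± 0.127 to 49.6 ± 2.83 CPM, and the cuticle collagen gene col-113 rose by 4.91 ± 0.20. Of 16187 tested genes 5378 were higher and 4834 lower at 26 °C.

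Cell cycle and DNA replication genes fell in 40 of 42 cases and rose in 1 (41 and 1 adjusted over the list alone; median -1.34). The ribonucleotide reductase gene rnr-1 fell by 2.14 ± 0.16 on the log2 scale and the phosphatase gene cdc-25.1 fell 4.59-fold, while the one that rose was cki-1, a cyclin-dependent kinase inhibitor (0.84 ± 0.17). The list test gave adjusted p = 1.67e-12, and adjusted p = 0.141 with an estimated correlation. Oocyte and maternal genes fell in 34 of 39 cases and rose in 1 (35 and 1 adjusted over the list alone; list test adjusted p = 1.62e-09, and adjusted p = 0.186 with an estimated correlation), among them the eggshell gene cpg-1 (-2.29 ± 0.17) and egg-3 (-2.14 ± 0.18). Germ granule genes fell in 24 of 28 cases and rose in 0 (24 and 0 adjusted over the list alone; list test adjusted p = 1.88e-07, and adjusted p = 0.2 with an estimated correlation), with mip-1 at -2.76 ± 0.19 and glh-4 at -2.52 ± 0.21. Meiosis genes fell in 30 of 35 and rose in 0 (30 and 0 adjusted over the list alone; list test adjusted p = 5.29e-11, and adjusted p = 0.141 with an estimated correlation), with the chromosome axis gene htp-3 at -2.13 ± 0.16. Germline small RNA genes fell in 27 of 32 and rose in 3 (27 and 3 adjusted over the list alone; list test adjusted p = 3.84e-07, and adjusted p = 0.19 with an estimated correlation), with the Argonaute gene wago-1 down 5.30-fold and ppw-2 up by 1.58 ± 0.28. Early zygotic genes fell in 22 of 26 and rose in 0 (23 and 0 adjusted over the list alone; list test adjusted p = 3.93e-07, and adjusted p = 0.141 with an estimated correlation), with pes-10 at -1.89 ± 0.20 and the T-box gene tbx-38 at -2.04 ± 0.25.

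Most listed chromatin regulators fell too. NuRD and MEC genes fell in 8 of 10 cases and rose in 0 (8 and 0 adjusted over the list alone; list test adjusted p = 0.00266, and adjusted p = 0.194 with an estimated correlation), with rba-1 at -1.14 ± 0.16 and lin-53 at -1.42 ± 0.16. In the NURF list isw-1 fell by 1.20 ± 0.16 whereas nurf-1 had a log2 fold change of 0.27 ± 0.20 (adjusted p = 0.264). Of the list, 4 of 6 members fell and 0 rose (4 and 0 adjusted over the list alone), and the list test gave adjusted p = 0.051. The synMuv B and DREAM list had 15 of 16 members lower and 0 higher (15 and 0 adjusted over the list alone), with dpl-1 at -1.44 ± 0.16 (list test adjusted p = 2.23e-05, and adjusted p = 0.141 with an estimated correlation). The list of MES and germline chromatin genes had 8 of 9 lower and 0 higher (8 and 0 adjusted over the list alone), with the methyltransferase gene set-25 at -1.80 ± 0.18 (list test adjusted p = 0.00145, and adjusted p = 0.173 with an estimated correlation). Endoplasmic reticulum and mitochondrial chaperone genes fell in 17 of 23 cases and rose in 1 (17 and 1 adjusted over the list alone; list test adjusted p = 0.000251, and adjusted p = 0.15 with an estimated correlation), with the mitochondrial protease gene clpp-1 at -1.17 ± 0.16. Apoptosis and engulfment genes fell in 12 of 25 cases, with ced-9 at -1.51 ± 0.18, and rose in 1, egl-1 (2.12 ± 0.46; 12 and 1 adjusted over the list alone; list test adjusted p = 0.0107, and adjusted p = 0.15 with an estimated correlation). Histone genes fell in 36 of 41 cases and rose in 1 (36 and 1 adjusted over the list alone, list test adjusted p = 0.000193, and adjusted p = 0.421 with an estimated correlation). Their summed level was 12606 CPM outside ribosomal RNA in the 20 °C replicate with 73.9% ribosomal RNA. It was 3476 CPM in the other, against 3422 and 3611 CPM at 26 °C. A few genes, among them his-71 and his-72, held 2220 and 2538 CPM of the 20 °C sums and 2728 and 2424 CPM of those at 26 °C. The fall in the sum thus rests on the 1 library at 20 °C with 73.9% ribosomal RNA. Without it the median log2 fold change of the list was -0.56 instead of -3.77.

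Many markers of differentiated tissues rose. Pharyngeal genes rose in 16 of 24 cases and fell in 2 (16 and 2 adjusted over the list alone; list test adjusted p = 0.00102, and adjusted p = 0.141 with an estimated correlation), with the troponin C gene tnc-2 at 2.04 ± 0.16 (19.2% of its exon bases overlap a gene on the opposite strand). Neuronal genes rose in 32 of 57 and fell in 6 (32 and 6 adjusted over the list alone; list test adjusted p = 0.00286, and adjusted p = 0.141 with an estimated correlation), among them the SNAP-25 gene ric-4 (2.15 ± 0.17). Ciliary genes rose in 32 of 41 and fell in 2 (33 and 2 adjusted over the list alone; list test adjusted p = 6.84e-05, and adjusted p = 0.141 with an estimated correlation), with bbs-8 at 2.95 ± 0.34 and che-13 at 1.63 ± 0.17. Intestinal genes rose in 19 of 32 and fell in 4 (19 and 4 adjusted over the list alone; list test adjusted p = 0.00414, and adjusted p = 0.141 with an estimated correlation); lys-1 rose by 3.58 ± 0.22, and end-1, a gene of early endoderm specification, fell by 1.19 ± 0.25. Body wall muscle genes rose in 22 of 40 and fell in 2 (22 and 2 adjusted over the list alone; list test adjusted p = 0.00612, and adjusted p = 0.19 with an estimated correlation), with the myosin light chain gene mlc-3 at 1.70 ± 0.18. Cuticle collagens rose in 79 of 137 and fell in 3 (78 and 3 adjusted over the list alone; list test adjusted p = 2.76e-08, and adjusted p = 0.326 with an estimated correlation).

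Many defence and detoxification genes also rose at 26 °C within the mutant. Innate immune effectors rose in 20 of 25 cases and fell in 0 (20 and 0 adjusted over the list alone; list test adjusted p = 1.84e-05, and adjusted p = 0.15 with an estimated correlation), with cnc-4 at 6.61 ± 0.30 and nlp-29 at 4.04 ± 0.22. The intracellular pathogen response list had 16 of 19 higher and 0 lower (18 and 0 adjusted over the list alone; list test adjusted p = 3.91e-05, and adjusted p = 0.141 with an estimated correlation), with skr-3 at 1.35 ± 0.17. Cytochrome P450 and UGT genes rose in 57 of 117 and fell in 12 (56 and 12 adjusted over the list alone; list test adjusted p = 0.00305, and adjusted p = 0.15 with an estimated correlation). Vitellogenin genes rose in 4 of 6 cases and fell in 0 (4 and 0 adjusted over the list alone; list test adjusted p = 0.0399, adjusted p = 0.19 with an estimated correlation, and 0.0567 without 20 °C mutant replicate 2, with a median of 6.08 against 5.36).

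Heat shock genes were split in this comparison. Of 27 members 14 rose, 4 fell and 9 did not pass, and the list test did not pass the threshold (adjusted p = 0.133; 14 and 4 adjusted over the list alone). The small heat shock genes hsp-12.3 and hsp-17 rose by 5.03 ± 0.30 and 5.05 ± 0.37, hsp-70 rose by 1.60 ± 0.16, and the oocyte and embryo heat shock gene sip-1 fell by 2.69 ± 0.22. Opposite-strand genes overlap 13% of the exon bases of hsp-17 and 19.2% of those of sip-1. hsp-110 and dnj-13 had log2 fold changes of 0.25 ± 0.18 and 0.21 ± 0.16 (adjusted p = 0.24 and 0.285). Ribosomal protein genes rose in 2 of 77 cases and fell in 7 (0 and 6 adjusted over the list alone; adjusted p = 0.419).

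The largest single rises started from libraries with almost no reads. cnc-11 had 2366 reads at 26 °C and 0 at 20 °C, at least 337-fold higher against a floor of 3 counts over the group. The neuropeptide-like gene nlp-27 was at least 214-fold higher and spig-4 at least 116-fold. kreg-1 had 1604 reads against 2, a ratio of 343 with a counting interval from 94.7 to 2830. The largest falls included the glutamine synthetase gene gln-6 (-3.28 ± 0.20), the glyceraldehyde-3-phosphate dehydrogenase genes gpd-4 (-3.27 ± 0.19) and gpd-1 (-3.11 ± 0.21), which are close copies that can share reads, and the Y-box gene cey-2 (-3.14 ± 0.21). Without 26 °C mutant replicate 1 or 2, 2570 or 2722 genes were lower instead of 4834.

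**Figure D3:**
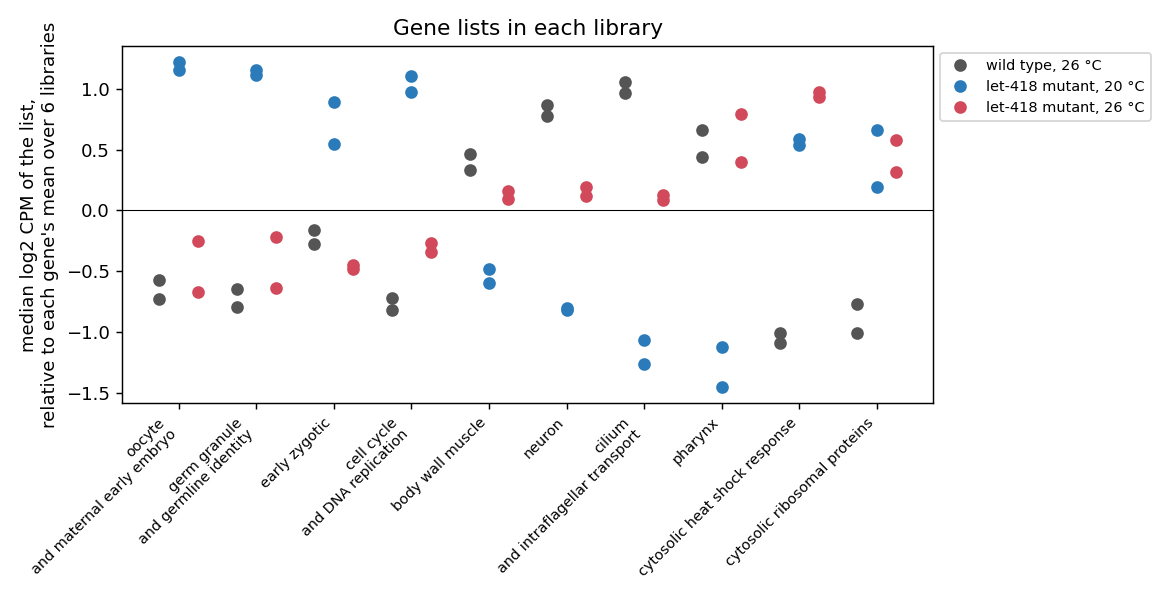
Median log2 CPM of 10 gene lists in each of the 6 libraries, relative to each gene's mean over all libraries; points are libraries. The maternal list lies at 1.15 and 1.22 in the 20 °C mutant and below 0 in the other 4 libraries, and the heat shock list at -1.01 and -1.10 in wild type and above 0 in the 4 mutant libraries.

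Genes called in both comparisons against the 26 °C mutant were counted next. In the 26 °C mutant, 1071 genes were higher than in both other groups and 607 lower than in both. Independent lists of these sizes would share 1133 and 791 genes, and simulated unchanged groups sharing the same libraries gave 0 and 0 in 20 simulations. All groups had the same means in these simulations, so their values show only what noise in shared libraries gives. Without real changes few genes can be called, so the 0 shared genes were nearly fixed in advance. Another 1416 genes were higher than in wild type and lower than in the 20 °C mutant, against 1019 for independent lists, and 1092 were the reverse, against 880. Across genes the fold changes correlated at 0.06, and at 0.443 on average in the simulations, while their covariance was 0.127 against 0.07 simulated. Both same-direction counts lie below those of independent lists. Both comparisons use the same 2 libraries of the 26 °C mutant, which could not be split. Genes higher than in both groups included sod-5 (3.63 ± 0.26 against wild type and 3.17 ± 0.27 against the 20 °C mutant), the galectin gene lec-6 (2.93 ± 0.21 and 3.72 ± 0.23) and col-42 (2.89 ± 0.28 and 3.66 ± 0.34). Genes lower than in both included fbxb-17 (-2.23 ± 0.20 and -1.77 ± 0.20), the acyl-CoA dehydrogenase gene acdh-1 (-1.38 ± 0.21 and -1.58 ± 0.21) and ego-1, an RNA-dependent RNA polymerase gene of the germ line (-1.31 ± 0.23 and -1.42 ± 0.24).

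The third comparison, the 20 °C mutant against 26 °C wild type, differs in both genotype and temperature and is given as values. Heat shock genes were higher in 22 of 27 cases and lower in 4 even though these embryos were kept at the lower temperature (22 and 4 adjusted over the list alone; list test adjusted p = 2.3e-05, and adjusted p = 0.118 with an estimated correlation). hsp-70 was 18.7-fold higher, at 147 ± 13.4 CPM (SD, n = 2), and nurf-1 3.38-fold higher, at 1864 ± 174 CPM. Ribosomal protein genes were higher in 73 of 77 cases and lower in 0 (74 and 0 adjusted over the list alone; list test adjusted p = 5.63e-13, and adjusted p = 0.376 with an estimated correlation). Cell cycle genes were higher in 41 of 42 and lower in 0 (41 and 1 adjusted over the list alone), with pcn-1, the PCNA gene, at 3.07 ± 0.18 (list test adjusted p = 8.87e-13, and adjusted p = 0.118 with an estimated correlation). All 6 NURF list members were higher (6 and 0 adjusted over the list alone), with isw-1 at 1.51 ± 0.17 (list test adjusted p = 0.00259, and adjusted p = 0.148 with an estimated correlation). Ciliary genes were lower in 37 of 41 cases and higher in 1 (37 and 1 adjusted over the list alone), with bbs-2 at -3.20 ± 0.22 (list test adjusted p = 1.47e-07, and adjusted p = 0.118 with an estimated correlation). Germ granule genes were higher in 24 of 28 cases (24 and 0 adjusted over the list alone; list test adjusted p = 1.83e-07, and adjusted p = 0.213 with an estimated correlation) and maternal genes in 31 of 39, with 1 lower (31 and 1 adjusted over the list alone; list test adjusted p = 1.57e-08, and adjusted p = 0.178 with an estimated correlation). In all, 5262 genes were higher and 5967 lower by edgeR's quasi-likelihood test; leaving ribosomal RNA genes out moved the median log2 fold change of all genes from -0.22 to -0.38, with 4532 higher and 6456 lower.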

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

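The tests on ribosomal RNA, copies, the mutant genotype, embryo age, adult tissue and the length correction in this part were chosen only after the result was seen. Those on length-matched genes were set before.

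Signals outside the main comparisons stood above their level in wild type, reads placed at several positions in 4 mutant libraries and ribosomal RNA in 3. The share of alignments at several places was 36.6% and 3.43% in the 20 °C mutant replicates 1 and 2, and 4.4% and 15.05% in the 26 °C mutant replicates 1 and 2, against 1.65% and 1.62% in wild type. The ribosomal RNA share of gene counts was 73.858% and 1.461% in the 20 °C mutant and 21.637% in 26 °C mutant replicate 2, against 0.383% and 0.281% in wild type. Small nucleolar RNAs summed to 858 CPM outside ribosomal RNA in 20 °C mutant replicate 1 and to 157 CPM in replicate 2.

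Heat shock genes were higher in the 26 °C mutant than in 26 °C wild type, with a median log2 fold change of 1.84. Without both libraries rich in ribosomal RNA, which leaves 1 library of the 26 °C mutant, the median was 1.88 (list levels of 0.98 in 26 °C mutant replicate 1 and 0.94 in the rich replicate 2), and over the 19 members without a near-identical copy it was 1.62, so neither accounts for the pattern. Other genes matched on exon length and level had a median of 0.3 (quartiles 0.14 and 0.52), too small for a length bias. The mutant genotype is a candidate explanation, since 22 of 27 members were also higher, and 4 lower, in the 20 °C mutant. That comparison differs in temperature as well, and the maternal and ciliary lists shifted in it, so it does not isolate the genotype. A separate handling of the wild-type libraries may also give the same values. Genotype and handling cannot be told apart, because both mutant groups are compared with the same 2 wild-type libraries.

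Ciliary genes were lower and ribosomal protein genes higher in the 26 °C mutant than in 26 °C wild type, and fold changes in this comparison followed exon length. With each library's length trend removed the medians were -0.66 (quartiles -0.97 and -0.4) for ciliary genes and 0.94 (0.77 and 1.06) for ribosomal protein genes, and both lists passed the test at the preset correlation, which argues against length as the whole cause; before that correction an estimated correlation gave adjusted p = 0.0843 and 0.441. Length- and level-matched genes had medians of -0.38 (quartiles -0.64 and -0.16) and 0.64 (0.55 and 0.78), so whether length bias makes up at least 0.5 of each shift cannot be told apart from a shift of the lists themselves. Younger embryos in the 26 °C mutant cannot be told apart from these either. Cuticle collagen genes, which younger embryos should hold at lower levels, were higher (median 0.82, list test adjusted p = 0.441 with an estimated correlation). That list was taken by gene name and not by stage, so its rise cannot date the embryos. Early zygotic genes (2 higher, 8 lower) went against the explanation by younger embryos, but did not pass the list test at the preset correlation (adjusted p = 0.197). Maternal genes were near even (6 higher, 5 lower). Cell cycle genes (21 higher, 0 lower) and neuronal genes (14 lower, 6 higher) went with it. With an estimated correlation their list tests gave adjusted p = 0.232 and 0.178.

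Within the mutant, early lists were lower and differentiation lists higher at 26 °C than at 20 °C. The share of ribosomal RNA orders the 4 libraries across both groups. Histone genes aside, 21 of 21 lists called at the preset correlation (0 with an estimated one) had a gap between groups larger than the differences within them. These lists were chosen as called between the same libraries, which favours such a gap. The result therefore argues only weakly against ribosomal RNA as their cause. For histone genes, also called, the difference within a group, 3.54, was larger than the gap of 0.3. The part of ribosomal RNA in their fall cannot be told apart. Adult tissue would bring abundant vitellogenin RNA, but the 6 genes summed to 15.9 CPM at 26 °C and 2.3 CPM at 20 °C. Older embryos at 26 °C and an effect of the temperature itself cannot be told apart, since each group was made at 1 temperature. The 10 of 10 lists that went as older embryos would are those of the pattern itself and so do not support that explanation.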

How the results depend on the processing

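Fits without ribosomal RNA genes, without both libraries rich in them, with equal depth, with a length correction and with a crossed block were chosen after seeing the data. Leaving out a library leaves an arm with 1 library assumed to vary like the others. Such fits also ended calls of picked genes beyond those mentioned above. Against wild type, the 26 °C mutant then had 933 to 4164 higher genes (main 3411) and 783 to 4040 lower (main 2649). Against the 20 °C mutant it had 4585 to 5827 higher and 2570 to 4757 lower (main 5378 and 4834). The 20 °C mutant against wild type had 3568 to 5155 higher and 4810 to 6606 lower (main 5262 and 5967). Over all settings the range within the mutant was 4119 (CPM filter) to 5827 higher and 2570 to 5118 (length correction) lower, and in the third comparison 3568 to 5512 (length correction) higher and 4499 (CPM filter) to 6825 (both libraries rich in ribosomal RNA left out) lower. With only the 4 libraries compared, 4034 genes were lower in the 26 °C mutant than in wild type; the cause was not tested. The replicate number as a block gave 3296 higher and 2531 lower in that comparison, 5148 and 4774 within the mutant, and 5190 and 5843 in the third. Replicate deviations correlated at 0.095, -0.021 and -0.109 between groups and so gave no sign that the numbers pair the samples. Each mutant group holds a library rich in ribosomal RNA, which can hide pairing, so a shared batch is not excluded. A crossed block within the mutant gave 5336 and 5016. With the correlation of list members estimated, 0 lists passed higher and 0 lower in each comparison, where the preset correlation gave 11 and 5, 10 and 12, and 15 and 9; at the smallest the adjusted p was 0.0843. Reversed results were ifta-1 within the mutant (log2 fold change 0.15; leave-outs from -1.02 to 0.15) and, in the third comparison, vit-4 (-2.73; from -2.73 to 4.09) and msp-36 (-1.93; from -1.93 to 5.98), all without 20 °C mutant replicate 2, and the F-box list within the mutant, called higher by fry (adjusted p = 0.0269); the cause was not tested. Over the list tests of all comparisons, fry gave the same outcome in 79, ended 2 calls, added 11 and reversed 1. The calls it ended were those of histone genes at 26 °C against wild type and within the mutant (fry adjusted p = 0.138 and 0.0938). Thinned to 5266529 counts outside ribosomal RNA, 2951 and 2079 genes were called in the first comparison, 4411 and 4094 within the mutant and 4589 and 5001 in the third.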

Other observations

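The test in this part that rests on exon length was chosen after seeing the data. Several lists held both directions against wild type at 26 °C. In the epidermis list the molting gene mlt-8 was higher by 1.62 ± 0.20 and the fusogen gene aff-1 lower by 1.49 ± 0.18, with 5 of 40 members higher and 9 lower (list test adjusted p = 0.1). Pharyngeal genes were higher in 5 of 24 cases and lower in 3, with pha-1 at -1.58 ± 0.21 (adjusted p = 0.926), and intestinal genes higher in 8 of 32 and lower in 3, with the protease gene cpr-4 at 3.78 ± 0.33 and the peptide transporter gene pept-1 at -1.10 ± 0.16 (adjusted p = 0.541). Apoptosis genes were higher in 8 of 25 and lower in 4 (8 and 5 adjusted over the list alone; adjusted p = 0.69), MES and germline chromatin genes higher in 4 of 9 and lower in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.1), and sperm genes higher in 2 of 17 and lower in 0 (adjusted p = 0.435). Of the Hox list 1 of 7 was higher (adjusted p = 0.958), and of 12 mitochondrially encoded genes 2 were higher (0 adjusted over the list alone; adjusted p = 0.69). Of the 4 major sperm protein genes measured, too few for the list test, 2 were higher, with msp-36 at 59 reads against 1, a ratio of 86.9 with a counting interval from 15 to 3490; that call ended without wild-type replicate 2 (adjusted p = 0.0593).

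Within the mutant, the list for the epidermis was split, with 16 of 40 higher at 26 °C and 8 lower (adjusted p = 0.277); wrt-1 was higher by 1.51 ± 0.16. Of the Hox list mab-5 was higher (1.42 ± 0.20), and 2 of 7 were higher and 3 lower (adjusted p = 0.743). Sperm genes were higher in 3 of 17 and lower in 3 (2 and 3 adjusted over the list alone; adjusted p = 0.789), excretory and glial genes higher in 8 of 21 and lower in 1 (adjusted p = 0.271), and F-box and MATH-BTB genes higher in 80 of 313 and lower in 82 (74 and 82 adjusted over the list alone; adjusted p = 0.681). No mitochondrially encoded gene of 12 and no major sperm protein gene of 4 passed the edgeR test.

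The gene nurf-1 was higher than in wild type in both mutant groups. Both comparisons use the same wild-type libraries, so they are not independent results. The 20 °C mutant also differs from wild type in temperature. It had 541 and 563 CPM in wild type, 1741 and 1987 CPM in the 20 °C mutant and 2378 and 2102 CPM in the 26 °C mutant. With the length trend removed, as with every other setting tried, its call against wild type at 26 °C held. These settings do not separate the genotype from the handling of the wild-type libraries, which was not tested.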
